A study of Mus musculus with 9 samples.

How the data were processed

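RNA was measured in microglia sorted from the brains of mice aged 2 to 3 months. Per the labels' protocols, mice received 5 mg/kg lipopolysaccharide (LPS, a component of the bacterial cell wall that sets off an inflammatory response) into the peritoneum, and brains were taken 72 hours (3 days) later after perfusion. Cortex and hippocampus were dissociated, and the tissue label reads cortex. Myelin was removed, astrocytes were first taken out on magnetic beads against the astrocyte surface antigen ACSA-2, and CD11b-bearing cells were then collected from the remaining fraction. CD11b is also carried by monocytes, neutrophils and NK cells, so the sort does not exclude them. The libraries came from a stranded kit for polyadenylated RNA, per the labels' protocols. The study made a conditional knockout (cKO) of the chromatin remodeller gene Chd8 in astrocytes, so the sorted microglia are not the cells in which the gene was targeted.

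The 9 samples fall into 3 groups of 3, taken from the genotype and treatment labels: control mice given saline, control mice given LPS, and cKO mice given LPS. All 9 titles hold the word saline, and those of the 3 cKO samples name the group as cKO saline where their genotype and treatment labels say LPS. The names of the authors' deposited comparisons say LPS for the cKO, so LPS was used. Microglia of cKO mice given saline were not analysed here. The labels number the samples within a group without saying that each came from a separate mouse, so p-values measure the spread between these samples, which may in part be technical. No replicate pair agreed within sampling noise, with chi-square values per degree of freedom over genes from 38.8 to 228.

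The authors deposited a table of normalized signal, gene counts divided by size factors, for 23134 genes in the 9 samples. Per the submitters' processing notes, the tools were Trimmomatic, FastQC, STAR, MultiQC 1.12, featureCounts, RSEM, edgeR 3.30.3 and DESeq2, with genome build mm10. Their roles, their order, the annotation and whether the strand was used in counting are not given in the sources used here. The authors also deposited 3 tables of comparisons with log2 fold changes, standard errors, p-values and adjusted p-values. Every deposited value was a whole multiple of its library's smallest step to within 0.01 of a read (100% of values), so whole reads were recovered as counts. These gave 10845937 to 86571481 reads per library. DESeq2 run on the recovered reads gave log2 fold changes within 4.84e-06 of the authors' deposited table of cKO LPS against control LPS, and the adjusted p was equal to within 1e-06 for 22785 of 22785 genes that had one in both. Start and end positions are given 1-based from the RefSeq annotation of GRCm38.p6, the same assembly as mm10. The ends were equal to those of the authors' deposited tables for 16575 of 16575 tested genes, and the authors' starts were 1 lower for 15724.

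The main test was limma-trend (R 4.3.3, limma 3.58.1) on log2(value + 1), with genes kept where the mean over the 9 libraries was at least 10. This left 16575 genes. A single fit over all 9 libraries with 6 residual degrees of freedom gave 3 contrasts, with Benjamini-Hochberg adjustment within each and a threshold of 0.05 on adjusted p. Fold changes are on the log2(value + 1) scale and understate the change of low genes. Where a group had no read of a gene, the fold is given as at least the ratio to a floor of 3 reads over the group, which is not an exact bound. Where it had 1 to 3 reads, the ratio of reads is given with an exact 95% interval. These intervals and floors cover counting error only. Coverage of the low genes differed, since the saline group held the fewest reads.

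Gene lists were fixed before the data were examined: 17 lists of pathways and microglial states and 15 lists of markers for cell types that the sort could hold. Of these 32, 31 had at least 4 tested members; the erythroid list had fewer and was not tested. Each list was tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 31 lists within a contrast. Beside it stand camera with an estimated correlation and fry, which tests whether a list's genes move on balance one way. No list's median changed when genes unread in a group were set at their bound. Genes to be named were also fixed in advance: the 6 largest rises and 6 largest falls among genes with adjusted p under 0.05, a mean of at least 50, no overlap between the libraries of the groups and no clone name, then a panel of 14 genes, then up to 4 members with the smallest adjusted p of each list described. The genes called by DESeq2 or by a single alternative for cKO LPS against control LPS, Slc1a2, Xist, and the grouping of genes by the stem of their symbols were chosen after their values were seen. Lists share some members, such as Lcn2 in the cytokine and the reactive astrocyte list.

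The share of the LPS response present in cKO LPS was the slope across genes of the cKO LPS effect on the control LPS effect, both against the same saline libraries, with the variance and covariance that sampling spread adds taken off. Same-numbered saline and cKO LPS samples deviated together from their group means, with correlations of 0.387, 0.242 and 0.35, so for cKO LPS against control saline the numbers may pair the samples, although the labels state no shared litter, batch or day. Sex was read from Xist, with a library called female above 1000 normalized counts. By that call all libraries numbered 2 were male and all numbered 3 female. The number thus ran in part with sex, and the correlations of same-numbered samples cannot fully tell a pairing from sex. The fit was tested on simulated data with 200 changed genes among the real ones. For control LPS against saline it called 21.5%, 66.7% and 75.8% of genes changed by 1, 2 and 3 on the log2 scale, and 6 of 16142 unchanged genes. For cKO LPS against control LPS the shares were 16.7%, 56.2% and 77.8%, with 2 of 16131 unchanged genes called, and for cKO LPS against saline 16.4%, 66.7% and 78.5%, with 2 of 16133. A shifted list was called in each of the 3 contrasts, and of the 30 other lists 1, 0 and 0 were called. The simulated genes were drawn independently of each other and no library was set apart. The real lists had estimated correlations up to 0.923, so the simulated rates of wrong calls do not carry over to them. In the real data control LPS library 1 stood apart and all contrasts shared a single estimate of spread. The simulated shares of changed genes called therefore need not hold for the real comparisons. The slope came back as 0.5 and 1 where it had been set to 0.5 and 1. Without the correction it came back as 0.5 and 0.89, so only the setting of 1 tested the correction.

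Alternatives set before the data were examined were a pseudocount of 8, no filter and a minimum mean of 50, rescaling by TMM factors, quantile normalization, a fit on 6 libraries, the replicate number as a block, array weights, an added minimum of 1 on the absolute log2 fold change, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, and each library left out in turn. Sex as a covariate, the mean of the neutrophil list as a covariate, and edgeR, the sex covariate or the estimated correlation with control LPS library 1 left out were added after seeing the data. Figures were drawn with matplotlib 3.10.9.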

Results

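Microglia, the resident macrophages of the brain, were profiled by RNA sequencing from control mice given saline, control mice given LPS, and mice with an astrocyte cKO of Chd8 given LPS, with 3 libraries per group. The series asks how loss of Chd8 in astrocytes alters gene expression at rest and in neuroinflammation, and these libraries address the microglial side of it under LPS. Values are counts normalized by the authors, given as mean ± SD with n = 3 per group unless stated otherwise. Reads recovered from the deposited values numbered 34356433, 25878146 and 10845937 in the saline libraries, 38442204, 52373652 and 42201860 in control LPS and 33661096, 47274412 and 86571481 in cKO LPS. The saline group was thus the shallowest, which limits precision for genes that are nearly silent without LPS. Xist, transcribed from the inactive X chromosome, marked 2 saline libraries, 1 control LPS library and 1 cKO LPS library as female.

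Chd8 itself was measured at 5041, 6596 and 4252 normalized counts in the saline libraries, 5507, 5408 and 5842 in control LPS and 5214, 6219 and 5453 in cKO LPS. Its log2 fold change between cKO LPS and control LPS was 0.0078 (SE 0.16, limma adjusted p = 0.9999). The gene lies on chromosome 14 from 52198151 to 52258042 (mm10). The deletion was made in astrocytes and gene-level counts do not resolve a deleted exon, so this value does not check the genotype labels.

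Control LPS library 1 carried many transcripts of astrocytes. Slc1a2, the main astrocyte glutamate transporter, was read at 34073 normalized counts there and at no more than 445 in any of the other 8 libraries, and the mean log2 value of the astrocyte list was 12.2 against 6.06 to 8.28 elsewhere. Other lists set this library apart from control LPS libraries 2 and 3 as well. Its mean for choroid plexus and ependymal markers was 10.1 against 5.77 and 6.90 there, with 10.8 in saline library 1. For mural cell markers it was 10.7 against 8.78 and 8.23, with 10.6 in cKO LPS library 1. For oligodendrocyte precursor markers it was 9.89 against 7.91 and 8.55, with 9.80 in saline library 3. Relative to control LPS libraries 2 and 3, its median member lay at -2.59 for the neutrophil list, -2.22 for the monocyte list and -1.25 for the proliferation list on the log2 scale, but at -0.05 for homeostatic microglia and -0.18 for the type I interferon list. On the first principal component (46.7% of variance) it lay at -57.3, beside the saline libraries (-87.0 to -60.8) and away from the other 5 LPS libraries (21.5 to 78.6).

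**Figure D1:**
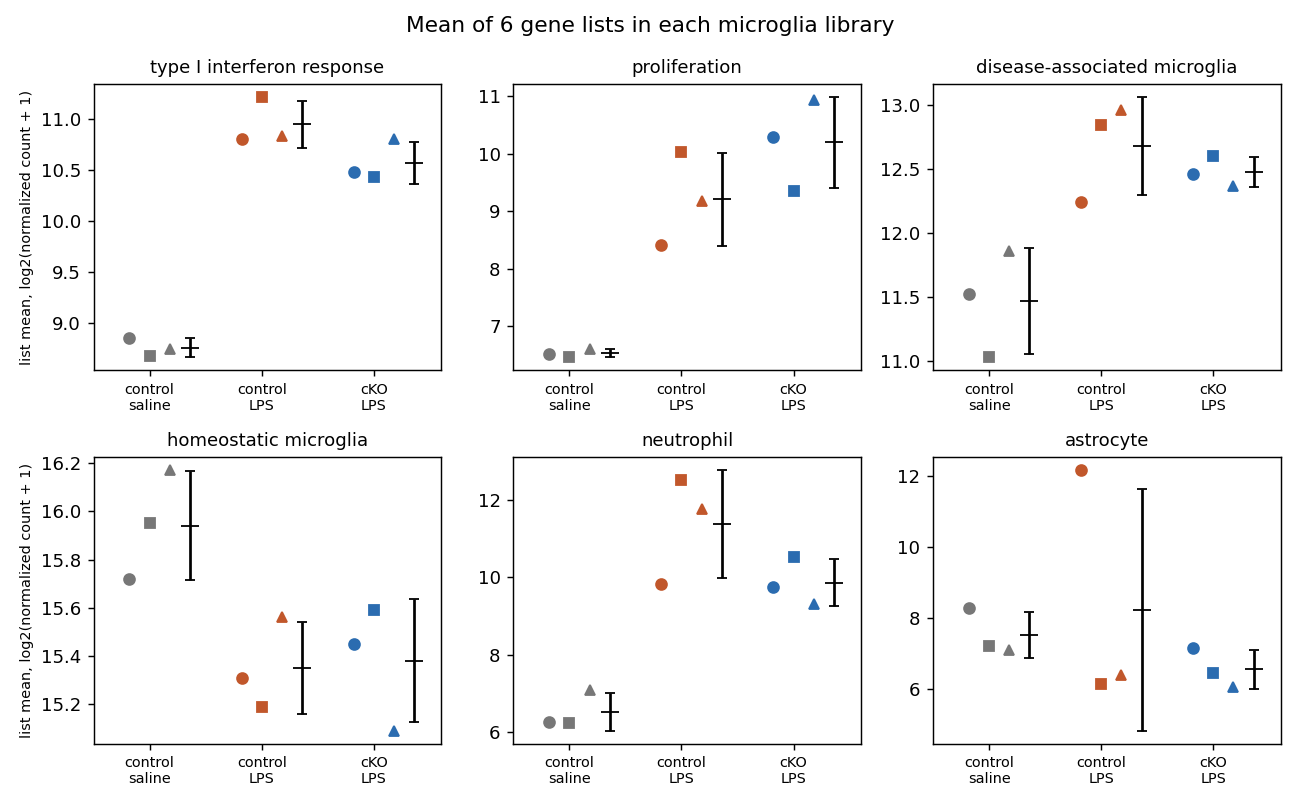
Mean log2(normalized count + 1) of chosen gene lists in each of the 9 libraries, by group. Shown are the type I interferon response, proliferation, disease-associated microglia, homeostatic microglia, neutrophil and astrocyte lists. Markers stand for replicates 1, 2 and 3 and bars for the group mean ± SD. Control LPS library 1 reaches 12.2 in the astrocyte list and 9.83 in the neutrophil list, where the other control LPS libraries stand at 6.16 and 6.39 and at 12.5 and 11.8.

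The first comparison, control LPS against control saline, gives the change in the CD11b-sorted cells of control mice 3 days after LPS. Neutrophil and monocyte markers rose in them, so a changed mix of cells may hold part of the changes below. Which cells carried a given change was not tested. Of 29 interferon-induced genes 28 rose, with a list median of 2.30 on the log2 scale, and 17 of 23 genes of cell division rose. Some complement genes (6 of 13) and cytokine genes of innate immunity (9 of 23) rose too, as did 10 of 11 neutrophil, 8 of 10 monocyte and 3 of 9 T and NK cell markers. Among genes of resting microglia 1 of 19 fell, at a list median of -0.59, and 4 of 20 immediate-early genes fell. These lists were called with a preset correlation and none of them with an estimated correlation, where the smallest adjusted p = 0.101. In all, 929 of 16575 genes changed (limma, adjusted p under 0.05), 776 higher and 153 lower.

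None of the type I interferon response genes fell, and 29 rose when adjusted over the list alone. Mx1, an antiviral GTPase, went from 142 ± 19.6 to 1646 ± 324 normalized counts (log2 fold change 3.52, SE 0.17, limma adjusted p = 8.275e-05), and Zbp1, a sensor of unusual nucleic acids, from 80.7 ± 20.0 to 1235 ± 409. Ifit3 rose 7.19-fold and Ifit2 9.69-fold, both encoding interferon-induced proteins that restrict viral RNA, and the panel gene Isg15, an interferon-induced ubiquitin-like protein, rose 5.82-fold. The list was called with a preset correlation (camera adjusted p = 1.06e-40) and by fry (adjusted p = 0.000136), but not at adjusted p = 0.101 with an estimated correlation. Genes of MHC class I presentation moved the same way, with 4 of 11 rising (7 adjusted over the list alone) and a median of 0.79. Among them were Nlrc5, the transactivator of class I genes, at 2.28, and the peptide transporter subunit Tap1 at 0.87. That call had adjusted p = 0.201 with an estimated correlation. MHC class II genes, with a median of -0.09 and the panel gene Cd74 at -0.23 (adjusted p = 0.795), gave no call.

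The NF-kB and cytokine list had 9 of 23 members rising and none falling (10 and 1 adjusted over the list alone). Saa3, an acute-phase serum amyloid on chromosome 7 from 46711998 to 46719615, had the largest rise of the comparison. It gave 3 reads over the saline libraries and 145865 over control LPS, a ratio of 27890 after scaling (95% interval 9542 to 135200), and reached 39313 ± 29450 normalized counts. Lcn2, an iron-sequestering acute-phase protein, rose 79.6-fold, Il1rn, the interleukin 1 receptor antagonist, 12.9-fold and Il1b 5.61-fold. Tnf, by contrast, stood at 22031 ± 1217 in saline and 23208 ± 8199 after LPS (adjusted p = 0.985). Chemokine genes rose in 4 of 12 cases (7 adjusted over the list alone), with Ccl5 at 5.38, Cxcl10 at 2.21 and Cxcl16 at 1.81 on the log2 scale. Cxcl13, which attracts B cells, had 3 reads in saline against 1111, a ratio of 212.4 (95% interval 72.49 to 1032), while Ccl2 was not called at 0.32 (adjusted p = 0.723). Of 13 complement genes 6 rose, by either adjustment, led by C3 (100.6 ± 26.0 to 6466 ± 3500, log2 fold change 5.87), Cfb (6.16) and C4b (4.44). These 3 lists were called by the preset correlation, with medians of 0.69, 1.16 and 0.69, and had adjusted p = 0.271, 0.267 and 0.267 with an estimated correlation.

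Markers of dividing cells rose in 17 of 23 cases, by either adjustment, with a list median of 3.22. Mki67, the proliferation antigen, went from 181 ± 8.95 to 3202 ± 1850 normalized counts, and Ccnb2 and Ube2c, both of mitosis, rose 15.5-fold and 19.4-fold. Disease-associated microglia genes rose in 7 of 20 cases (9 adjusted over the list alone), with Axl, a receptor for apoptotic cells, at 2.69, the integrin Itgax at 2.80 and the cystatin Cst7 at 3.00. Apoe, of lipid transport, rose from 48806 ± 23530 to 195310 ± 96260 (adjusted p = 0.035). Lysosome genes rose in 4 of 18 cases (9 adjusted over the list alone, median 0.51), among them the protease genes Ctsl and Ctsz. With an estimated correlation these 3 lists had adjusted p = 0.267, 0.267 and 0.267.

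Homeostatic microglia genes were negative in 19 of 19 cases (median -0.59), but only Slc2a5, a fructose transporter, fell past the threshold over all genes (2.11-fold, adjusted p = 0.0303), and 6 did so when adjusted over the list alone. P2ry12, the purinergic receptor of resting microglia, stood at 91005 ± 33210 in saline and 44225 ± 14690 after LPS (log2 -1.03, SE 0.33, adjusted p = 0.116), with Cx3cr1 at -0.69 (adjusted p = 0.184) and Tmem119 at -0.52 (adjusted p = 0.200). The authors' deposited table called all of them lower, with adjusted p = 0.0232 for P2ry12, 0.00436 for Cx3cr1 and 0.0252 for Tmem119. The list's call had adjusted p = 0.267 with an estimated correlation. Immediate-early genes, which respond to stimulation and to tissue dissociation, fell in 4 of 20 cases (9 adjusted over the list alone; median -0.79), Jund by 1.24 and Egr2 by 1.45 on the log2 scale, with adjusted p = 0.267 with an estimated correlation. The largest falls lay elsewhere. Retnla, a marker of alternative macrophage activation, fell 34.5-fold, the lectin genes Cd209a and Mgl2 fell 16.5-fold and 6.77-fold (Retnla and Mgl2 resting in part on saline library 3, from -5.11 to -3.68 and from -2.76 to -2.15 on the log2 scale without it), and Gpr165, Ccl24 and Slc5a10 fell 4.99-fold, 4.63-fold and 4.47-fold.

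Markers of other cells of the blood rose with LPS. Of 11 neutrophil markers 10 rose (11 adjusted over the list alone; median 5.16), with the granule gene Ngp from 91.6 ± 63.7 to 4567 ± 2603 and the calprotectin genes S100a8 and S100a9 at 5.75 and 5.05. Monocyte markers rose in 8 of 10 cases (9 adjusted over the list alone; median 3.96), with Itga4, Hp and Plac8 at 2.64, 5.08 and 4.06. T and NK cell markers rose in 3 of 9 cases (8 adjusted over the list alone; median 3.24), namely the granzymes Gzma and Gzmb and the granule protein gene Nkg7. The T cell genes Cd3e, Cd3d, Cd3g and Cd8a of that list were not among the tested genes. Its rise thus cannot be assigned to T cells. With an estimated correlation the 3 lists had adjusted p = 0.24, 0.267 and 0.267. The other large rises were in genes that myeloid cells can express, and which cells carried them here was not tested. Marco, a scavenger receptor on chromosome 1 from 120474538 to 120505024, had no read in saline and 12843 in control LPS, at least 2433-fold higher by the floor of 3 reads. Mpo, the neutrophil peroxidase, was at least 169-fold higher, Stfa2 at least 743-fold and Stfa3 at least 294-fold, and Cstdc5 had 1 saline read against 3408, a ratio of 1955 (95% interval 350.6 to 77230). The last 3 belong to a cluster of similar stefin genes on chromosome 16 whose reads the authors' counting could have split, so their values are uncertain. Stfa2 stood at 34.6 normalized counts in control LPS library 1 against 2066 and 1166 in libraries 2 and 3, whereas Mpo stood at 367 there against 221 and 157. Exact 95% intervals of the ratio of reads began lower than the floors, at 1997 for Marco, 137 for Mpo, 637.8 for Stfa2 and 254.5 for Stfa3.

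**Figure D2:**
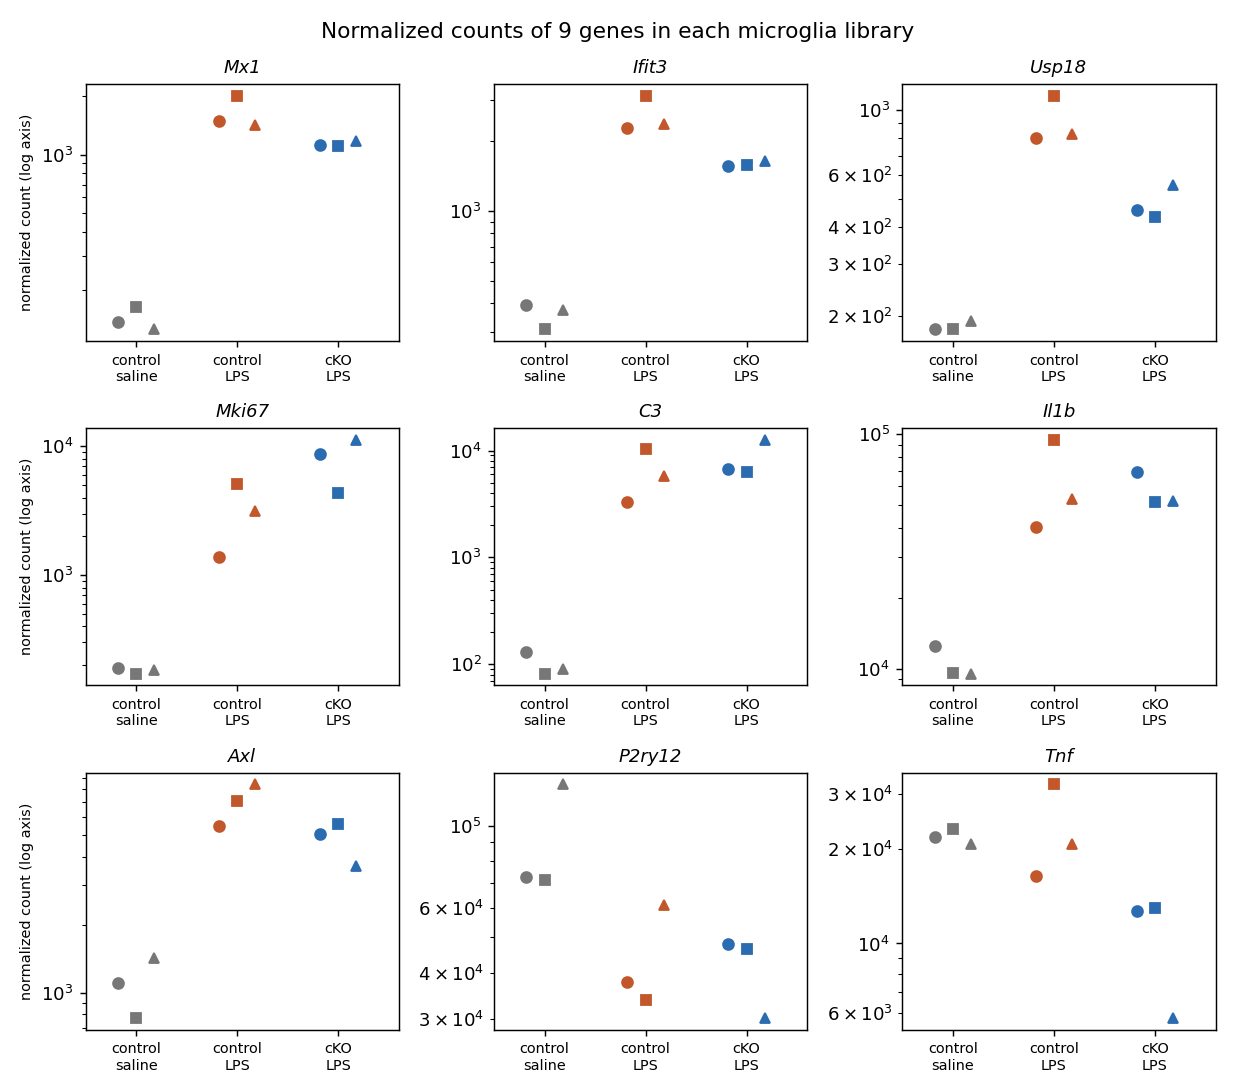
Normalized counts of 9 genes in each of the 9 libraries, on log axes, by group, with markers for replicates 1, 2 and 3. Mx1 rises from 142 in saline to 1646 in control LPS and stands at 1134 in cKO LPS, while P2ry12 goes from 91005 to 44225 and 41563.

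Of the remaining lists, reactive astrocyte (median 1.49), B cell (2.36), glycolysis (0.52), oxidative phosphorylation (0.34) and cytosolic ribosomal protein (0.61) were called higher with a preset correlation. Oligodendrocyte (-0.55), mural cell (-0.75), endothelial cell (-0.59), neuron (-0.38) and TGF-beta pathway (-0.20) lists were called lower. With an estimated correlation these 10 had adjusted p from 0.267 to 0.606, and none of the 31 lists was called that way, while fry called 15. No call was made for the lists of cholesterol synthesis (0.16), alternative activation (0.64), astrocyte (1.05), oligodendrocyte precursor (-0.56), border-associated macrophage (0.48), choroid plexus and ependymal (-1.63) and sex-linked genes (3.39). Some of these gained a call in alternatives. The alternative activation list did so in 7 (lowest adjusted p = 0.0166), oligodendrocyte precursor lower without saline library 1 (-0.77) or control LPS library 1 (-0.87), choroid plexus lower without control LPS library 1 (-2.91) and with the replicate number as a block, and border-associated macrophage higher without saline library 3 (0.87). With the neutrophil covariate, cholesterol synthesis (0.75) and MHC class II (-1.79) gained one, and oligodendrocyte precursor was called higher (2.10). Calls were lost for oxidative phosphorylation without saline library 2 (0.13) or control LPS library 2 (0.22), TGF-beta without saline library 2 (-0.16) or control LPS library 1 (-0.11), reactive astrocyte without the same libraries (1.18 and 1.30), B cell without saline library 2 (1.98) and mural cell without control LPS library 3 (-0.34). Medians also moved where calls stayed, complement to 0.38 without control LPS library 2, oxidative phosphorylation to 0.55 and TGF-beta to -0.32 without saline library 3, and mural cell to -1.55, oligodendrocyte to -0.89 and neuron to -0.59 without control LPS library 1, while oligodendrocyte weakened to -0.34 without library 2. The neuron call was lost without saline libraries 2 (-0.38) or 3 (-0.48) or control LPS libraries 2 (-0.35) or 3 (-0.43), and the endothelial call without saline libraries 1 (-0.34) or 3 (-0.53) or control LPS library 3 (-0.25). The astrocyte list was called lower without control LPS library 1 (-1.07) and higher without library 2 (1.80) or 3 (2.18). Over its 15 alternatives it was called higher in 3, and the lowest camera adjusted p of any was 6.44e-17. Gfap of the panel, an astrocyte filament gene, had 61.2 ± 34.0 in saline and 500 ± 751 after LPS, the latter resting on control LPS library 1.

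The authors' deposited table called 1770 genes in this comparison, 1384 higher and 386 lower, and held 928 of the 929 called here. Groups did not overlap in 3591 genes (21.7%), where 10% is the share by chance. Single libraries moved the count. It became 499, 418 and 562 without saline libraries 1, 2 and 3, and 1826, 387 and 374 without control LPS libraries 1, 2 and 3. A fit on the 6 libraries alone gave 417 genes, array weights gave 2789 (68.9% higher), and quantile normalization 811 (70.0% higher against 83.5%), with the median of all genes at -0.104. Of the 9 fits that left a library out, Apoe kept its call in those without saline library 3 or control LPS library 1 (adjusted p from 0.00828 to 0.124 over its alternatives, 0.0508 with the replicate number as a block), and Slc2a5, Jund, Egr2, Ctsl, Ctsz, Retnla, Mgl2, Stfa3, Cstdc5, Gzma and Nkg7 lost theirs in 3 to 7. Large rises moved with single libraries of control LPS. Without library 1 the log2 fold changes became 14.52 for Saa3, 12.25 for Marco, 10.60 for Stfa2, 10.02 for Cstdc5, 9.24 for Stfa3 and 7.28 for Lcn2. They became 6.81 for S100a8, 5.97 for S100a9, 6.23 for Ngp, 6.10 for Hp, 4.77 for Plac8, 5.21 for Gzmb, 4.40 for Gzma and 4.26 for Nkg7. Leaving out library 2 gave 12.93 for Saa3, 7.67 for Stfa2, 6.87 for Cstdc5, 6.13 for Stfa3, 5.05 for S100a8, 4.45 for S100a9, 4.27 for Hp and 3.06 for Il1rn, and leaving out library 3 gave 3.63 for Gzmb, 3.03 for Nkg7 and 2.87 for Gzma.

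The second comparison, cKO LPS against control LPS, asks what loss of Chd8 in astrocytes does to microglia under LPS. No single gene changed by the test used here. As groups, and with a preset correlation only, genes of cell division were called higher in cKO LPS at a median of 1.16, and type I interferon genes (-0.33), neutrophil markers (-1.21) and astrocyte markers (-1.71) lower. With an estimated correlation these had adjusted p = 0.427, 0.427, 0.427 and 0.935, and fry gave 0.961 for each, while the astrocyte median turned to 0.26 without control LPS library 1. Homeostatic (0.03) and disease-associated (-0.08) microglia genes gave no call, and neither did the NF-kB and cytokine (-0.06) or complement (-0.01) lists. In alternatives 18 of the 23 lists without a call gained one. Among them were choroid plexus and ependymal in 6, MHC class II in 5, cytosolic ribosomal protein in 4, disease-associated microglia in 3 and homeostatic microglia in 2. The NF-kB and cytokine list and the complement list gained one in 1 alternative each.

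Type I interferon genes were lower in 28 of 29 cases, though none passed over all genes and 4 were lower when adjusted over the list alone. Usp18, which restrains interferon signalling, had 916 ± 175 normalized counts in control LPS and 483 ± 66.3 in cKO LPS, against 185 ± 6.61 in saline. Ifit3 stood at 2598 ± 473 and 1595 ± 42.1 (log2 -0.69, SE 0.15), Ifit2 at 3007 ± 698 and 1726 ± 26.9 and Isg15 at 1121 ± 473 and 673 ± 102. The list was lower with a preset correlation (camera adjusted p = 1.61e-18), with adjusted p = 0.427 with an estimated correlation and 0.961 by fry (range over its alternatives 9.31e-25 to 0.961). Its median was -0.43 without control LPS library 1, -0.21 without control LPS library 2 and -0.52 without cKO LPS library 3, with the call kept.

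Proliferation genes were positive in 23 of 23 cases, with 1 higher when adjusted over the list alone and none over all genes. Mki67 stood at 3202 ± 1850 and 8085 ± 3470 normalized counts (log2 1.42, SE 0.46, adjusted p = 0.9999), Cenpf at 598 ± 176 and 1466 ± 472, and Cenpe at 603 ± 248 and 1434 ± 569. The list's adjusted p was 1.84e-23 with a preset correlation, and it had adjusted p = 0.427 with an estimated correlation. Its median without control LPS library 1, which was low in these genes, was 0.72.

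Neutrophil markers were negative in 11 of 11 cases, none of them called over all genes or over the list alone. Ngp stood at 4567 ± 2603 in control LPS and 850 ± 502 in cKO LPS, the lactoferrin gene Ltf at 3276 ± 1931 and 612 ± 480, and Camp at 464 ± 249 and 90.0 ± 73.0. The list was called lower with a preset correlation (2.52e-09), with adjusted p = 0.427 with an estimated correlation. The mean log2 value of the list was 9.83, 12.5 and 11.8 in control LPS libraries 1 to 3 and 9.75, 10.5 and 9.31 in cKO LPS, and without control LPS library 2 its median was -0.62. Astrocyte markers were negative in 15 of 15 cases, with adjusted p = 0.935 with an estimated correlation, and turned to a median of 0.26 without control LPS library 1. Mural cell markers (0.64) were called higher, and glycolysis (-0.14), immediate-early (-0.27) and oligodendrocyte (-0.31) genes lower, each with adjusted p = 0.935 with an estimated correlation. The oligodendrocyte call was lost without control LPS library 1 or cKO LPS library 1 or 2 (medians -0.08, -0.23 and -0.12), the mural call without control LPS library 2 or 3 or cKO LPS library 1 (medians 0.31, 0.08 and 0.33), the immediate-early call without control LPS library 3 or cKO LPS library 3 (-0.20 and -0.08), and the glycolysis call without control LPS library 2 or 3 or cKO LPS library 1 or 2 (0.02, -0.12, -0.10 and -0.06). Where calls stayed, medians moved to -2.88 (astrocyte) and -0.54 (oligodendrocyte) without control LPS library 2, to 1.44 (mural) and -0.26 (glycolysis) without control LPS library 1, and to -0.62 (oligodendrocyte) and -0.24 (glycolysis) without cKO LPS library 3.

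**Figure D3:**
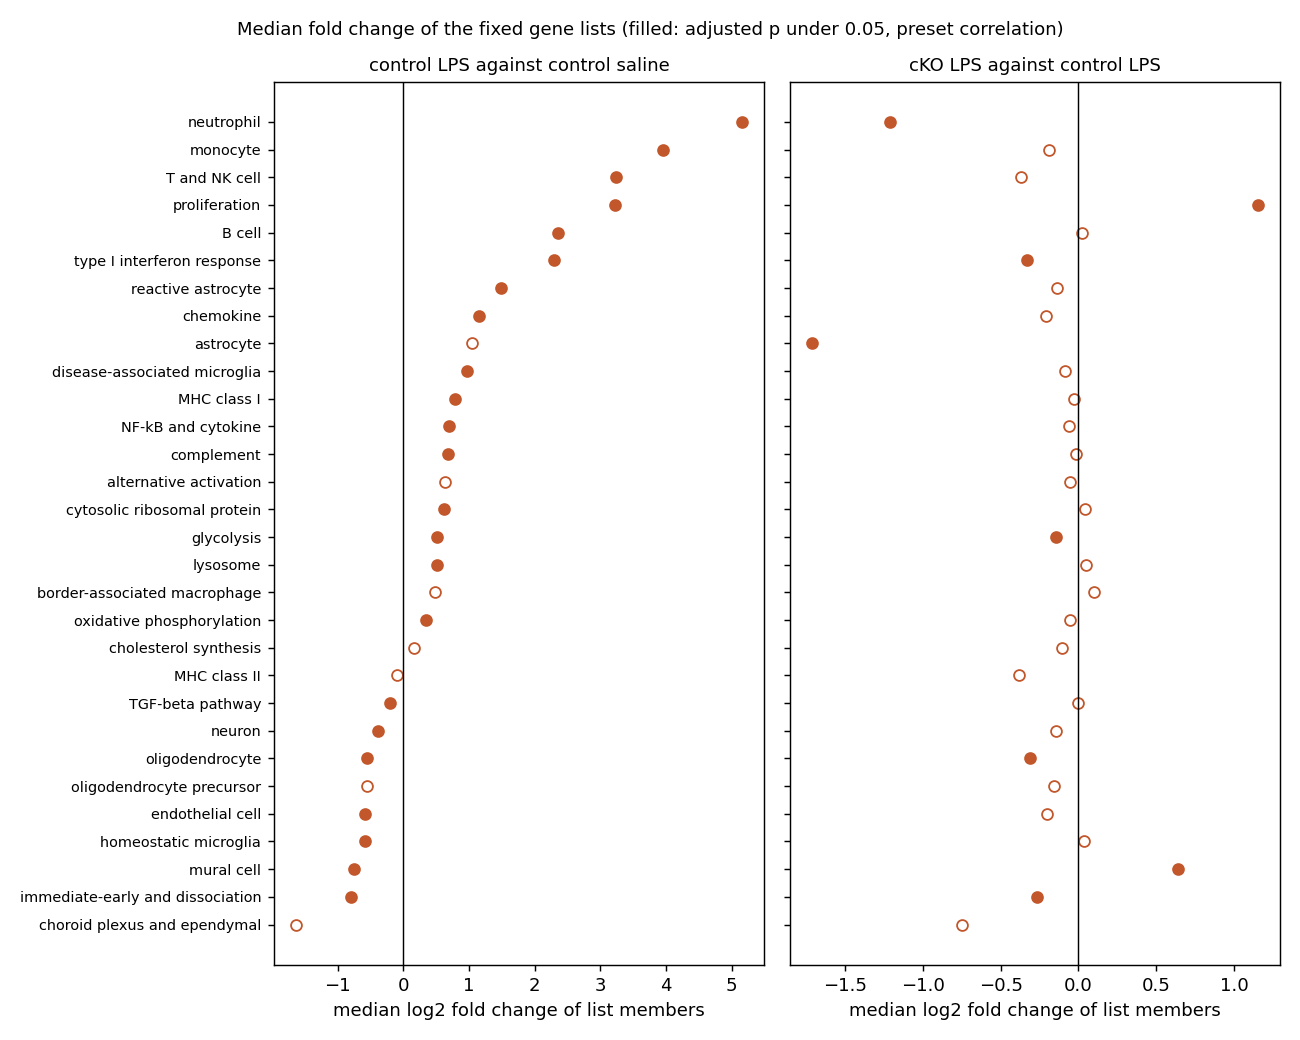
Median log2 fold change of the members of each tested list but the sex-linked one, for control LPS against saline and for cKO LPS against control LPS. Points are filled where camera with a preset correlation gave adjusted p under 0.05. The type I interferon list lies at 2.30 and -0.33 and the proliferation list at 3.22 and 1.16.

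Without control LPS library 1, which leaves 2 control LPS libraries, other lists moved below control LPS as well. Monocyte markers had a median of -0.96, T and NK cell markers -1.13, chemokine genes -0.40, disease-associated microglia genes -0.36, NF-kB and cytokine genes -0.22, complement genes -0.18, oxidative phosphorylation genes -0.19, ribosomal protein genes -0.18 and MHC class II genes -0.43, all called lower with a preset correlation, and oligodendrocyte precursor (0.37) and astrocyte markers (0.26) were called higher. None of the 31 lists was called with an estimated correlation when that library was left out, and the smallest adjusted p = 0.133. Neutrophil markers then stood at -2.16.

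Among panel genes, Tnf had 23208 ± 8199 normalized counts in control LPS and 10486 ± 4081 in cKO LPS (log2 -1.18, SE 0.33, adjusted p = 0.9999), and C3 6466 ± 3500 and 8533 ± 3516. Il1b (-0.04), Apoe (0.06), P2ry12 (-0.07), Tmem119 (-0.04), Cx3cr1 (0.18), Ccl2 (-0.10), Cxcl10 (-0.34), Cd74 (-0.43) and Gfap (-0.82) did not pass either. The authors' deposited table called 4 genes, which were named after their values were seen. Gdf15, a stress-induced cytokine, was at -1.18 (adjusted p = 0.0265), Usp18 at -0.92 (adjusted p = 0.0336), Hsd11b1, which regenerates active glucocorticoid, at -1.54 (adjusted p = 0.0440), and the predicted gene Gm7335 at 3.87 (adjusted p = 0.0265), all from the authors' deposited table. In the limma fit they were at -1.16, -0.91, -1.62 and 3.11, each with adjusted p = 0.9999. Gdf15 was read at 641, 883 and 933 normalized counts in control LPS and 410, 348 and 329 in cKO LPS, and Hsd11b1 at 366, 401 and 370 against 115, 84.8 and 188. Gm7335 was read at 236 and 266 in cKO LPS libraries 1 and 2 but at 19.9 in library 3, and as a predicted gene whose reads similar copies may share it is uncertain.

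Limma called 0 of 16575 genes, with 263 at an unadjusted p under 0.05 where 829 would come by chance. That number was 639 without control LPS library 1, 411 with the replicate number as a block and 811 with array weights. With fewer small p-values than chance gives, the limma test was conservative here, so its 0 does not show an absence of effect. EdgeR called 0 (577 unadjusted) and DESeq2 the 4 above. The pseudogene Ncoa4-ps was called in 2 alternatives only, the fit on 6 libraries (limma adjusted p = 0.0306) and the one without saline library 3 (adjusted p = 0.00801), at -5.29 on the log2 scale in both. It was read at 286, 588 and 458 normalized counts in control LPS, 9.73, 10.6 and 9.34 in cKO LPS and 7.90, 6.93 and 706 in saline, and as a pseudogene whose reads similar copies may share it is uncertain. Groups did not overlap in 831 genes (5.01%, 10% by chance).

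The third comparison, cKO LPS against control saline, mixes genotype with LPS, since no cKO saline library was analysed. Interferon genes rose in 27 of 29 cases, proliferation genes in 17 of 23 and neutrophil markers in 8 of 11, in lists with adjusted p = 0.205, 0.282 and 0.282 with an estimated correlation. Saa3 and Marco again led the rises, and Retnla and Cd209a the falls. In all, 1131 genes changed, 897 higher and 234 lower.

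Interferon genes had a median of 1.87 (29 rising when adjusted over the list alone), with Mx1 at 1134 ± 41.2 normalized counts, 7.98-fold above saline, and Lgals3bp at 32249 ± 2410. Proliferation genes had a median of 4.30 (19 adjusted over the list alone), Mki67 rising 41.2-fold, Ube2c 40.8-fold and Ccnb2 35.2-fold. Neutrophil markers had a median of 3.55 (9 adjusted over the list alone), with S100a8 at 4.54 and S100a9 at 3.80, and disease-associated microglia genes rose in 7 of 20 cases (9 adjusted over the list alone; median 0.92), with Axl at 2.14 and Cd63 at 1.40. Immediate-early genes fell in 7 of 20 cases (12 adjusted over the list alone; median -0.94), Jund 2.83-fold, Ier2 2.20-fold and Egr1 3.43-fold. With an estimated correlation these 5 lists had adjusted p = 0.205, 0.282, 0.282, 0.295 and 0.282.

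Saa3 reached 114960 ± 56630 normalized counts (597607 reads against 3, ratio 90440, 95% interval 30950 to 438500), Marco was at least 4775-fold and Stfa2 at least 282-fold higher by the floor of 3 reads, and Lcn2 rose 225-fold. Exact 95% intervals of the ratio of reads began at 4978 for Marco and 266.7 for Stfa2. Cxcl13 had 1806 reads against 3, a ratio of 273.3 (95% interval 93.37 to 1327), and Cstdc5 1716 against 1, a ratio of 779.1 (139.6 to 30790). Retnla fell to 3 reads from 195, a ratio of 0.006985 (95% interval 0.001428 to 0.02072). Cd209a fell 25.8-fold, Ccdc162 20.4-fold, Mgl2 8.11-fold, Eps8l1 7.98-fold and Hbegf, a growth factor of the epidermal growth factor family, 5.42-fold. Of the panel, C3 rose by 6.35 on the log2 scale, Il1b by 2.44, Apoe by 2.06, Isg15 by 1.87 and Cxcl10 by 1.87. Tnf stood at -1.16 (adjusted p = 0.0745), called in 4 of its 13 limma alternatives. These were quantile normalization (0.0324), the replicate number as a block (0.0481), the fit without control LPS library 1 (0.046) and sex as a covariate (0.0461). P2ry12 stood at -1.10 (adjusted p = 0.0823), Tmem119 at -0.56 (adjusted p = 0.146) and Cx3cr1 at -0.51 (adjusted p = 0.288), and Chd8, Ccl2, Cd74 and Gfap were not called. The authors' deposited table called Tnf (adjusted p = 0.0210), P2ry12 (0.00958) and Tmem119 (0.0119) lower, but not Cx3cr1 (0.0588).

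With a preset correlation 16 lists were called higher and 6 lower, none with an estimated correlation and 14 by fry. The authors' deposited table called 2064 genes, with 1129 of the 1131, and groups did not overlap in 5258 genes (31.7%, 10% by chance). The count fell to 639, 591 and 709 without saline libraries 1, 2 and 3 and to 519, 588 and 490 without cKO LPS libraries 1, 2 and 3, while array weights gave 3182. Apoe, Cstdc5, Retnla, Mgl2, Ccdc162, Eps8l1, Hbegf, Cd63, Egr1 and S100a9 lost their calls in 3 to 7 of the 9 fits that left a library out, and Cxcl10 without cKO LPS library 1 (adjusted p = 0.0541). Without saline library 3 Retnla went from -5.69 to -4.26 and Mgl2 from -3.02 to -2.41 on the log2 scale. Leaving out cKO LPS library 3 gave 11.78 for Marco, 6.23 for Cxcl13, -4.09 for Cd209a, -3.70 for Ccdc162 and -1.96 for Eps8l1. Saa3 became 14.88 without saline library 2, Lcn2 8.43 without cKO LPS library 2, and Cd209a -5.31 without cKO LPS library 1.

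Both LPS groups were set against the same saline libraries. Across the 16575 genes, which are not independent replicates, their effects correlated at 0.88 where unchanged groups simulated against those libraries gave 0.50, and the covariance was 0.754 against 0.143, a difference of 0.611. Genes higher in both numbered 651 and lower in both 125, against 42 and 2.16 for independent lists of the same lengths, and none went opposite ways. A split of the 3 saline libraries would leave 1 of them in one part and was not made. Part of the correlation of 0.88 and of the overlap may therefore come from the shared controls. The simulated values of 0.50 and 0.143 hold that sharing, and the values for independent lists do not. The share of the control LPS response present in cKO LPS, corrected for sampling spread, was 1.20 (jackknife SE 0.411), with values from 0.888 without control LPS library 1 to 1.43 without control LPS library 2. Before that correction the slope was 0.948. As no cKO saline library was analysed, the slope also holds any effect of the genotype that is present without LPS.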

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

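The sex and neutrophil covariates and the fits with control LPS library 1 left out beside another change were chosen only after the data were seen, and the other settings before the data were examined. Of the named genes called, 43 of 61 kept their call in all 13 alternatives for control LPS against control saline and 24 of 37 for cKO LPS against control saline, and none of them turned direction. Of the lists called with a preset correlation, 4 of 23, 2 of 8 and 5 of 22 kept the call in all 13 alternatives that keep that test, for control LPS against saline, cKO LPS against control LPS and cKO LPS against saline. With an estimated correlation 0 lists kept a call in any comparison, and fry called 15, 0 and 14. Depth limits the genes near silent in saline, where the smallest library held 10845937 reads. Where a value moved, the cause was not tested unless a construction is named here.

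For genes changed, control LPS against control saline, the count of 929 became 417 with the 6 libraries of the comparison only, 2789 with array weights, 1770 with DESeq2, 1647 with the sex covariate and control LPS library 1 left out and 1837 with edgeR and that library left out. Leaving out single libraries gave 374 to 1826. For genes changed, cKO LPS against control LPS, the count of 0 became 1 with the 6 libraries only and 4 with DESeq2, and 0 to 1 with single libraries left out. For genes changed, cKO LPS against control saline, the count of 1131 became 3182 with array weights and 2064 with DESeq2, and 490 to 1656 with single libraries left out. The share of the LPS response stayed between 0.888 and 1.43.

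With the replicate number as a block the counts were 926, 0 and 1286. The number ran in part with sex, so the block also takes up part of any difference between the sexes. Same-numbered pairs correlated at 0.37, 0.0785 and 0.233 between saline and control LPS and at 0.468, -0.066 and 0.216 between control LPS and cKO LPS, so not every pair of these lay over 0.1, while 8 of 9 libraries correlated best with their own number. For cKO LPS against control saline, where every pair did, the block brought in Tnf (adjusted p = 0.0481) and the alternative activation list (0.0364), lost the reactive astrocyte list (0.0513) and changed no other call of a named gene or list.

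With quantile normalization the median of all genes moved to -0.104, 0.0255 and -0.0785 in the 3 comparisons, from 0.0169, -0.0179 and -0.00797, and these genes turned sign or these lists turned the direction of the camera test. That test sets a list against all other genes, so a median can keep its sign where the direction turns, here and below. After quantile normalization in control LPS against control saline: Chd8 -0.012 and Tnf -0.11. After quantile normalization in cKO LPS against control LPS: homeostatic microglia -0.0065, MHC class I -0.027, TGF-beta pathway -0.018, alternative activation -0.024, oligodendrocyte precursor -0.14, sex-linked 0.28 and Apoe -0.0042. After quantile normalization in cKO LPS against control saline: Chd8 -0.0069. With sex as a covariate these turned in the same sense. With sex in control LPS against control saline: sex-linked -0.057 and Tnf -0.14. With sex in cKO LPS against control LPS: MHC class I -0.030. By fry the direction differed from that of camera for these, whose medians are unchanged by construction. By fry in control LPS against control saline: MHC class II -0.094. By fry in cKO LPS against control LPS: MHC class I -0.030, alternative activation -0.052, oligodendrocyte precursor -0.16 and sex-linked 0.11.

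The neutrophil covariate takes the neutrophil list out by construction and runs with LPS. With it the camera test turned direction for these lists, given with their medians. With this covariate in control LPS against control saline: disease-associated microglia -0.39, lysosome -0.12, glycolysis -0.043, oxidative phosphorylation -0.34, cytosolic ribosomal protein -0.52 and alternative activation -0.72. Further: oligodendrocyte 1.13, oligodendrocyte precursor 2.10, neuron 0.12, endothelial cell 0.30, mural cell 2.18 and monocyte -0.15. Further: neutrophil -0.11, border-associated macrophage -0.64, T and NK cell -0.055, B cell -0.57 and choroid plexus and ependymal 3.31. With this covariate in cKO LPS against control LPS: disease-associated microglia 0.24, NF-kB and cytokine 0.0078, chemokine -0.11, MHC class II 0.065, complement 0.28 and glycolysis 0.062. Further: oxidative phosphorylation 0.14, oligodendrocyte precursor -1.05, mural cell -0.46, monocyte 0.84, neutrophil 0.37 and T and NK cell 0.37. With this covariate in cKO LPS against control saline: disease-associated microglia 0.017, glycolysis -0.028, oxidative phosphorylation -0.20, cytosolic ribosomal protein -0.11, alternative activation -0.29, astrocyte 5.56 and oligodendrocyte 0.37. Further: oligodendrocyte precursor 1.22, mural cell 1.85, neutrophil -0.064, border-associated macrophage -0.13, B cell 0.15 and choroid plexus and ependymal 0.53. Other calls were lost with this covariate without a turn of the test. Lost with it in control LPS against control saline: NF-kB and cytokine 0.25 (adjusted p = 0.869), chemokine 0.47 (adjusted p = 0.294), MHC class I 0.68 (adjusted p = 0.168), complement -0.19 (adjusted p = 0.741), TGF-beta pathway -0.52 (adjusted p = 0.104) and reactive astrocyte 1.08 (adjusted p = 0.201). Lost with it in cKO LPS against control LPS: immediate-early and dissociation -0.15 (adjusted p = 0.273). Lost with it in cKO LPS against control saline: NF-kB and cytokine 0.45 (adjusted p = 0.536), chemokine 0.15 (adjusted p = 0.199), complement -0.17 (adjusted p = 0.141) and lysosome 0.18 (adjusted p = 0.825). Further: neuron -0.068 (adjusted p = 0.906), endothelial cell -0.19 (adjusted p = 0.579), monocyte 0.51 (adjusted p = 0.741) and T and NK cell 0.35 (adjusted p = 0.741). With quantile normalization calls were lost without a turn as well. Lost so in control LPS against control saline: neuron -0.51 (adjusted p = 0.157) and endothelial cell -0.68 (adjusted p = 0.137). Lost so in cKO LPS against control saline: oxidative phosphorylation 0.19 (adjusted p = 0.0549) and neuron -0.74 (adjusted p = 0.0832). The neuron call of control LPS against control saline was lost with sex as a covariate (adjusted p = 0.0541), and the reactive astrocyte call there with the block (0.0645).

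With single libraries left out, the lowest and highest values of the genes that turned sign and of the lists and families whose camera test turned direction were as follows. In control LPS against control saline: Ccl2 from -0.042 to 0.61, Cd74 from -0.65 to 0.16, Chd8 from -0.047 to 0.27, MHC class II from -0.31 to 0.14, Tnf from -0.25 to 0.24, astrocyte from -1.07 to 2.18 and cholesterol synthesis from -0.046 to 0.28. In cKO LPS against control LPS: Apoe from -0.31 to 0.43, B cell from -0.43 to 0.43, Ccl2 from -0.44 to 0.13, Cfap family from -1.58 to 0.0023, Chd8 from -0.066 to 0.061, Dnah family from -1.91 to 0.12 and Gfap from -1.59 to 0.63. Further: Il1b from -0.32 to 0.30, MHC class I from -0.081 to 0.11, NF-kB and cytokine from -0.22 to 0.030, P2ry12 from -0.24 to 0.19, T and NK cell from -1.13 to 0.26, TGF-beta pathway from -0.058 to 0.084 and Tmem119 from -0.083 to 0.022. Further: alternative activation from -0.19 to 0.088, astrocyte from -2.88 to 0.26, chemokine from -0.40 to 0.12, cholesterol synthesis from -0.40 to 0.017, choroid plexus and ependymal from -1.48 to 0.33, complement from -0.18 to 0.068 and cytosolic ribosomal protein from -0.18 to 0.15. Further: disease-associated microglia from -0.36 to 0.063, endothelial cell from -0.83 to 0.22, homeostatic microglia from -0.083 to 0.17, lysosome from -0.060 to 0.14, monocyte from -0.96 to 0.23, neuron from -0.25 to 0.064 and oligodendrocyte precursor from -0.56 to 0.37. Further: oxidative phosphorylation from -0.19 to 0.031, reactive astrocyte from -0.32 to 0.44 and sex-linked from -3.17 to 3.75. In cKO LPS against control saline: Ccl2 from -0.14 to 0.51, Chd8 from -0.039 to 0.28 and cholesterol synthesis from -0.28 to 0.17. In cKO LPS against control saline, calls of these lists were lost without a turn when single libraries were left out: glycolysis in 1 (adjusted p = 0.0925), oxidative phosphorylation in 2 (adjusted p from 0.268 to 0.577), reactive astrocyte in 2 (adjusted p from 0.0554 to 0.0621), neuron in 2 (adjusted p from 0.0637 to 0.0783), endothelial cell in 3 (adjusted p from 0.066 to 0.172) and choroid plexus and ependymal in 2 (adjusted p from 0.118 to 0.125).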

Other observations

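The grouping of genes by the stem of their symbols into 349 families of at least 6 tested members, and the tests on control LPS library 1, on the mix of sexes and on the neutrophil list, were chosen only after the result was seen. After LPS in control mice, 18 of the 349 families were called higher and 1 lower with a preset correlation. They held families of immune genes, some with members in the fixed lists, and others such as Rpl, Rps, Atp and Kif. Schlafen genes (Slfn), which act in immune cell growth and antiviral defence, had 5 of 8 members rising and a median of 1.69. Guanylate-binding proteins (Gbp), which act against intracellular pathogens, had 2 of 8 and 0.66, and the Ifitm genes, whose products block virus entry, 4 of 6 and 2.43. Klra genes, which encode Ly49 receptors of NK cells, had 2 of 7 and 2.97, and the C-type lectins (Clec) 7 of 22 and 0.68. These 5 had adjusted p = 0.993 with an estimated correlation, with adjusted p from 8.49e-05 to 0.993 over their alternatives. Slfn, Gbp, Klra and Ifitm are sets of similar paralogs, so how their reads were shared is uncertain.

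Between cKO LPS and control LPS, no family member passed over all genes. A preset correlation called 5 families higher and 2 lower, of which Cep, Haus and Rad, all higher, are not described further. The cell division cycle associated genes (Cdca) were higher with a preset correlation, at a median of 1.00, and lost that call without control LPS library 1 (0.59) or cKO LPS library 3 (0.58). The kinesins (Kif), motors of the spindle and of transport, were called higher at 0.059, a call lost with quantile normalization (0.092), with the replicate number as a block, and without saline library 2, control LPS library 3 or cKO LPS libraries 1 or 3 (adjusted p from 0.0662 to 0.419). Genes of motile cilia, Cfap at -0.77 and the axonemal dyneins Dnah at -1.07, were called lower and turned to 0.0023 and 0.12 without control LPS library 1. Their calls were also lost without saline library 2 or cKO LPS library 3 (-0.13 and -0.50 without the latter), and that of Dnah without cKO LPS library 2. All 4 had adjusted p = 1 with an estimated correlation.

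Control LPS library 1 stood apart from the other control LPS libraries. It held astrocyte RNA, with 12 of 15 astrocyte markers lying over 4 times above the highest of the other 8 libraries. Whether that RNA was carried through the sort stays open, since the values that prompted this explanation cannot also bear it out. That RNA as a dilution of all microglial transcripts is argued against for its lower neutrophil, monocyte and proliferation lists, since the neutrophil list lay 2.54 further below libraries 2 and 3 than the homeostatic list did. A saline library under an LPS label is argued against by its interferon list, whose median member lay 2.11 above the saline mean. A weaker entry of blood cells into that sample stays open and was not tested.

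Type I interferon genes were lower in cKO LPS than in control LPS, in a call lost with an estimated correlation (adjusted p = 0.427). RNA of neutrophils in the sort as the whole cause is argued against by the median with the neutrophil list as a covariate, -0.33 (limma camera adjusted p = 0.000718, against a range of 9.31e-25 to 0.961 over all alternatives). That adjusted p rests on a preset correlation. The covariate also differed between the groups, and its slope was drawn from 3 libraries in each. A share of neutrophil RNA in the difference therefore stays open. Control LPS library 1 alone is argued against by its list mean of 10.81, the lowest of control LPS (11.22 and 10.84 in the others, 10.48, 10.43 and 10.81 in cKO LPS). The median of -0.43 without it could be foreseen from that mean and adds no separate support. Leaving out control LPS library 2 narrowed the gap. An uneven mix of sexes is argued against by a difference of 0 females (1 female and 2 males in each group), a balance that also bound the sex covariate to leave the median at -0.33. A damped interferon response in microglia after loss of Chd8 in astrocytes, a response that differs between the sexes, and a difference between the 3 samples of each group by chance stay open. Without cKO saline libraries, a damped response to LPS cannot be told apart from a difference already present without LPS.

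The neutrophil list was lower in cKO LPS than in control LPS with a preset correlation only, with 0 of 11 members passing and adjusted p = 0.427 with an estimated correlation. High values in control LPS libraries 2 and 3 only were thought of from the list mean of control LPS library 1, 9.83, which lies inside the cKO LPS range of 9.31 to 10.5. Fewer neutrophils in the sort were thought of from 11 of 11 members being lower (interquartile range of their log2 fold changes 0.651 without that library). These values prompted the explanations and decide neither. Whether fewer neutrophils entered the brains of cKO mice or fewer were carried through the sort was not tested.

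Other splits of the 6 libraries of a comparison number 10 with the real one, too few to judge by. For genes changed, control LPS against control saline, 1 of 10 splits reached the real 929 (highest other 2). For genes changed, cKO LPS against control LPS, 10 of 10 reached the real 0, and for genes changed, cKO LPS against control saline, 1 of 10 reached the real 1131 (highest other 1).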
